A study of Homo sapiens with 12 samples.

How the data were processed

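Gene expression was measured in 12 samples of LX-2 cells, an established line of human hepatic stellate cells, the cell type that lays down scar matrix in injured liver. Cells had received a control siRNA or an siRNA against STAT3, and were either left untreated (0 h) or given TGF-b, a cytokine that activates stellate cells, at 4 ng/ml for 2 h, per the labels' protocols. The labels gave 4 groups of 3 samples: control siRNA at 0 h, control siRNA at 2 h, STAT3 siRNA at 0 h and STAT3 siRNA at 2 h. RNA was hybridised to a whole-transcript Affymetrix gene array, 1 array per sample. The series design says that no technical replicates were made. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples.

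The deposited values were read as log2 signals per probe set, already processed by the authors, with 1 column per sample. The labels do not state the log base, and the log2 scale was inferred from the range of the values. The background correction and normalization are not given in the sources used here, and Partek 6.6 is named in the submitters' processing notes without a role. The table held 352859 probe sets, and the medians of the 12 arrays lay between 5.598 and 5.645. The number of arrays limits the precision, and no slide or scan information was used here.

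Probe sets were assigned to genes through the platform annotation. A single gene symbol was listed for 259224 probe sets, several for 13116, and none for 80519, and only the first kind entered the gene values. Of 22320 symbols, 20529 were current in the RefSeq annotation of GRCh38.p14, 1726 were updated through a synonym and 65 were kept as listed. This left 22260 genes, 17902 of them protein-coding, with a median of 10 probe sets each. A gene's level was the mean of its probe sets on the log2 scale. Dim probe sets enter that mean, so fold changes of genes with such probe sets can be understated, and values of genes with 1 or 2 probe sets are less certain. Listed genes without a probe set of their own in the annotation used were not analysed here.

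Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) on all 12 arrays with a mean for each group, so that the groups share 1 estimate of the spread (8 residual and 4.17 prior degrees of freedom). The comparisons were STAT3 siRNA against control siRNA at 0 h and at 2 h, 2 h of TGF-b against 0 h with each siRNA, and the difference of the TGF-b responses (the interaction). The TGF-b effect averaged over both siRNAs served to choose responding genes. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within a comparison and a threshold of 0.05. Differences are log2, the first-named condition minus the second, and ± gives the SD over the 3 arrays of a group for levels. The change of response strength was measured on genes chosen by the averaged effect, which is independent of the interaction. Its p came from an exact test over 400 relabellings of the siRNAs within each time, and over fewer with 1 array left out. These relabellings stand for no siRNA effect of any kind. Effects of the siRNA common to both times therefore enter the relabelled values, and this p is not a test of equal responses alone.

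In total 20 gene lists were fixed before the data were examined: TGF-b/SMAD targets, BMP targets, extracellular matrix, STAT3 targets, JAK-STAT components, TGF-b receptors and SMADs, immediate-early genes, serum response and actin, inflammatory genes, interferon-stimulated genes, cell cycle, p53 targets, stress response, stellate identity, circadian clock, sterol synthesis, and markers of hepatocytes, macrophages, endothelium and cholangiocytes. Of their genes, 23 stood in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusted over the lists of a comparison. Counts of members were taken with adjustment over all genes and adjusted over the list alone. The genes named were STAT3, the 10 largest rises and 10 largest falls of each comparison among protein-coding genes that passed the test with non-overlapping groups (for the interaction, all that passed), and up to 4 members of each list with the smallest p. Other genes are named only where the text says that they were chosen after their values were seen.

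On simulated data with the real arrays' spread over 22260 genes, the test of STAT3 siRNA at 0 h recovered 0% of genes changed by 0.25, 52% at 0.5, 94% at 1 and 96% at 1.5 (log2). The interaction recovered 0%, 22%, 82% and 90% at those sizes. The adjusted threshold eases as more genes pass, so these shares do not carry over directly. The simulated siRNA test made 130 calls against 3047 in the real data, which understates its recovery. The simulated interaction made 105 calls against 4, which overstates it. Alternatives covered the replicate block, only the groups compared, eBayes with a trend or robust, a filter on the lowest 40% of genes, quantile normalization, median centring, the median or the brightest probe set per gene, a fold of at least 1.5, and leaving out each array. Leaving out dim probe sets was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.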

Results

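The study measured gene expression in LX-2 human hepatic stellate cells to ask how knockdown of STAT3, a transcription factor of cytokine signalling, changes the response to TGF-b. Each of the 4 groups (control or STAT3 siRNA, untreated or after 2 h of TGF-b) had 3 arrays. Arrays of a group correlated at r = 0.9684 to 0.9754 over all probe sets, and the lowest correlation between arrays of different groups was 0.9631. An untreated group at 2 h was not analysed here, so an effect of TGF-b includes whatever 2 further hours of culture changed.

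STAT3, the target of the siRNA, was lower in every array that had received it. Its level was 8.963 ± 0.0512 (SD, n = 3) with control siRNA and 8.177 ± 0.0881 with STAT3 siRNA at 0 h, a log2 difference of -0.79 with 58% of the signal left (limma adjusted p = 1.06e-05). After TGF-b the levels were 9.093 ± 0.0214 and 8.281 ± 0.011, a difference of -0.81 with 57% left (limma adjusted p = 8.85e-06). An exact permutation test of 3 against 3 arrays gave p = 0.1 at both times, the smallest p it allows. Of the 24 STAT3 probe sets, 21 were lower at 0 h and 22 at 2 h. TGF-b itself left STAT3 without a called change, at 0.13 with control siRNA and 0.10 with STAT3 siRNA (adjusted p = 0.435 and 0.705).

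**Figure D1:**
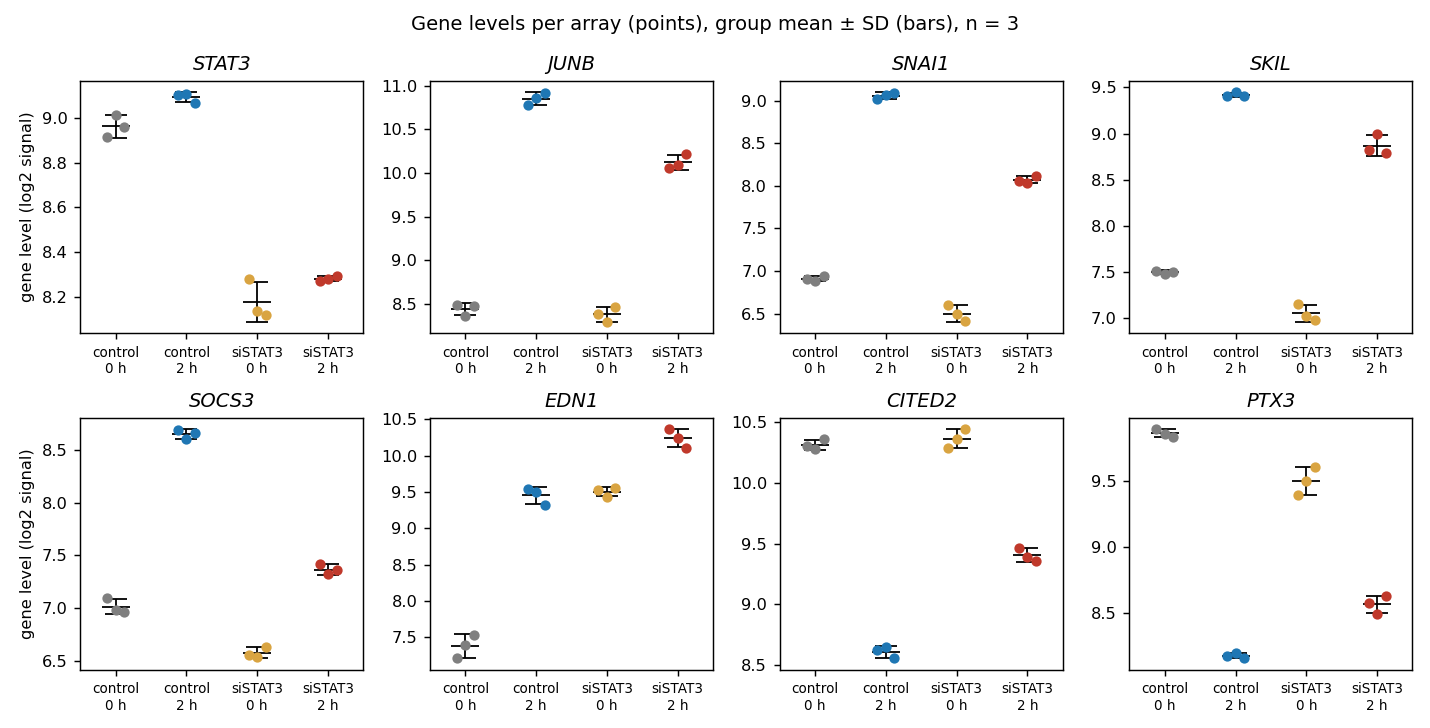
Gene levels (log2 signal, y axis) of STAT3, JUNB, SNAI1, SKIL, SOCS3, EDN1, CITED2 and PTX3 in the 4 groups (x axis). Points are arrays and bars give the group mean ± SD (n = 3). STAT3 is lower in all arrays with STAT3 siRNA, and EDN1 stands at 9.508 with STAT3 siRNA at 0 h, near the 9.454 reached by control cells after TGF-b.

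Without TGF-b, STAT3 siRNA raised ACTA2, the smooth muscle actin that marks activated stellate cells, 3.21-fold (log2 difference 1.68, adjusted p = 1.57e-06), and COL4A1, COL3A1 and COL1A2 rose 2.57-fold, 2.16-fold and 2.05-fold. EDN1, which encodes the vasoconstrictor endothelin-1, rose 4.37-fold, from 7.38 ± 0.162 to 9.508 ± 0.0655 (SD, n = 3). ALDH1L2, a mitochondrial folate enzyme, rose 4.63-fold and PSAT1, an enzyme of serine synthesis, 2.90-fold. GJA1, the gap junction protein connexin 43, was 4.28-fold lower, and the basement membrane gene NID1 was 3.49-fold lower. In all, 1387 genes rose and 1660 fell among 22260, and 51 of those that rose and 46 of those that fell did so at least 2-fold.

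The other largest rises were in B3GALT2 (1.71), RTL3 (1.54), the integrin subunit ITGB3 (1.52), TRIM58 (1.45) and SHLD2 (1.43). SHLD2 rests on 2 probe sets, as does H2BC15, which was also higher (adjusted p = 4.78e-05). The control level of H2BC15 (3.351) lay below the 25th percentile of probe sets on each array (3.717 to 3.786) and is not shown to be above background, so the size of its difference is not given. CTSS, a lysosomal protease, fell by 1.63 on the log2 scale and the chemokine gene CXCL16 stood at -1.47. UHMK1 (-1.47), VAT1L (-1.42), FAM91A1 (-1.30) and CASD1 (-1.29) were among the 10 largest falls. CDK11B (lower, adjusted p = 0.0345) rests on 1 probe set and did not pass when control siRNA 0 h replicate 1 or 2 or STAT3 siRNA 0 h replicate 2 or 3 was left out (highest adjusted p = 0.134). With STAT3 siRNA, CDK11B (3.51) and ACTBL2 (3.523), which also fell, lay below that percentile, so no sizes are given.

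Of 42 measured extracellular matrix genes, 22 rose and 3 fell (26 and 3 adjusted over the list alone), and the list stood above other genes (camera adjusted p = 1.54e-10; adjusted p = 0.0201 with an estimated correlation). Of 23 serum response and actin genes, 15 rose and none fell, with 15 and 1 adjusted over the list alone. TPM4 (1.03), TAGLN (0.85) and CNN1 (0.73) were among them. That list's call (camera adjusted p = 7.84e-10) was lost with the other setting, adjusted p = 0.0559 with an estimated correlation. Of 15 sterol synthesis genes, 10 fell and none rose (11 and 0 adjusted over the list alone), among them HMGCS1 (-0.54), STARD4 (-0.54), MSMO1 (-0.52) and IDI1 (-0.39). The sterol call held (camera adjusted p = 1.32e-07; adjusted p = 0.0201 with an estimated correlation).

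Of 21 genes of the unfolded protein and integrated stress responses, 8 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 2.06e-05; adjusted p = 0.0788 with an estimated correlation). PSAT1 (1.54), the cystine transporter SLC7A11 (1.15), asparagine synthetase ASNS (0.91) and XBP1 (0.84) had the smallest p. Of 36 cell cycle genes, 12 fell and 2 rose (18 and 2 adjusted over the list alone; camera adjusted p = 2.44e-05; adjusted p = 0.113 with an estimated correlation). The replication and G1/S genes CCNE1 (-0.71), CDC6 (-0.63), MCM6 (-0.54) and CCNE2 (-0.39) had the smallest p among the falls.

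STAT3 target genes went both ways at 0 h: of 36, 5 rose and 7 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.669). IL6ST, the shared receptor subunit of IL-6 cytokines, fell by 0.80 and SOCS3, a feedback inhibitor of STAT3, by 0.44, while GADD45B rose by 0.57. Among 29 JAK-STAT components 5 rose and 6 fell, with the adaptor GRB2 at -0.92, JAK1 at -0.40 and the receptor IL6R at 0.98. Among 26 TGF-b receptor and SMAD pathway genes 7 rose and 5 fell, with the BMP receptor BMPR1A at -1.13 and the activin antagonist FST at -0.70, against LTBP1 at 0.65 and ACVR1 at 0.51. TGF-b/SMAD targets were 6 up and 6 down out of 26, BMP targets 2 up and 2 down out of 11, and immediate-early genes 3 up and 2 down out of 30, with EGR1 at -0.81. Of 28 inflammatory genes 3 rose and 5 fell, with VCAM1 at -0.98. Of 36 interferon-stimulated genes 2 rose and 6 fell, with GBP1 at 1.16 and OAS1 at -0.59. Of 19 p53 targets 4 rose and 3 fell, and of 18 clock genes 3 rose. Adjusted over the list alone, 5 JAK-STAT genes rose and 9 fell, with 8 and 5 receptor and SMAD genes, 10 and 8 TGF-b/SMAD targets, 2 and 2 BMP targets, 4 and 2 immediate-early, 3 and 5 inflammatory, 3 and 8 interferon-stimulated, 4 and 3 p53 and 3 and 0 clock genes. None of these lists passed camera (adjusted p from 0.577 to 0.973). By fry, which asks whether a list moves one way on balance without comparing it with other genes, JAK-STAT components were called downward (adjusted p = 0.000472). Median and mean differed in sign for immediate-early genes (0.01 and -0.0024, with camera upward) and for cholangiocyte markers (0.00513 and -0.0355, with camera downward).

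Among 23 stellate identity genes FAP alone rose (adjusted p = 2.71e-05), also adjusted over the list alone. Its control level of 3.493 is not shown to be above background, so no size is given. This list, which covers stellate cell identity and activation, did not pass as a whole (camera adjusted p = 0.792). Its median log2 difference was 0.00273, with 12 of 23 members above 0. ACTA2, COL3A1 and COL1A2, which rose, are not among its measured members, so the list does not speak for them. Markers of other liver cell types did not pass as lists, with camera adjusted p = 0.577 for hepatocytes, 0.807 for macrophages, 0.867 for endothelium and 0.927 for cholangiocytes. Single members did move: the endothelial cadherin CDH5 rose by 0.53, TEK and TIE1 fell by 0.30 and 0.28, and the epithelial claudin CLDN4 fell by 0.76. With the median of a gene's probe sets in place of their mean, the number of changed genes at 0 h was 1718, and requiring a fold of at least 1.5 gave 635. TEK did not pass without control siRNA 0 h replicate 2 or 3 or STAT3 siRNA 0 h replicate 1 or 2 (highest adjusted p = 0.128), nor TIE1 without any one control siRNA 0 h array, STAT3 siRNA 0 h replicate 1 or 3 or STAT3 siRNA 2 h replicate 2 (0.141). With the median of probe sets CDK11B, JAK1, IDI1, MSMO1, ACVR1, OAS1, CDH5, TEK, TIE1 and CLDN4 no longer passed.

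With control siRNA, 2 h of TGF-b raised 17 of 26 immediate target genes measured. JUNB, an AP-1 subunit, rose 5.30-fold, from 8.444 ± 0.0715 to 10.85 ± 0.0713 (SD, n = 3; limma adjusted p = 5.46e-09), and SNAI1, a repressor of epithelial genes, rose 4.43-fold. EDN1 rose 4.21-fold, the SMAD corepressor SKIL 3.79-fold, PMEPA1 3.68-fold, the cytokine LIF 3.64-fold and the inhibitory SMAD7 3.47-fold. SOCS3 and BHLHE40 each rose 3.12-fold and TGFBI 2.97-fold. CITED2, a transcriptional coregulator, was 3.26-fold lower and the pentraxin PTX3 3.22-fold lower. In all, 394 genes rose and 210 fell, 31 and 17 of them at least 2-fold.

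The other largest falls were in KRTAP1-5 (-1.53), FAM24B (-1.35), LURAP1L (-1.33), NLRP10 (-1.21), TNFSF4 (-1.20), IL1B (-1.20), RGS4 (-1.15) and BMP4 (-1.13). FAM24B rests on 1 probe set. It did not pass when replicate 1 or 2 of either control group was left out (highest adjusted p = 0.107).

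Of the TGF-b/SMAD targets, 17 rose and none fell (22 and 0 adjusted over the list alone; camera adjusted p = 4.55e-49; adjusted p = 0.000134 with an estimated correlation). Of 11 BMP targets, 4 rose (7 adjusted over the list alone): ID1 by 1.30, SMAD6 by 0.99, NOG by 0.78 and BAMBI by 0.57 (camera adjusted p = 6.85e-10; adjusted p = 0.00481 with an estimated correlation). Of 36 STAT3 targets, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with GADD45B at 1.43 and VEGFA at 0.92 beside JUNB and SOCS3 (camera adjusted p = 1.06e-07; adjusted p = 0.0294 with an estimated correlation). Of 42 matrix genes, 9 rose and 1 fell (18 and 3 adjusted over the list alone; camera adjusted p = 6.90e-07; adjusted p = 0.0294 with an estimated correlation), with the smallest p for COL4A1 (0.71), LOX (0.53) and THBS1 (0.52). Of 30 immediate-early genes, 8 rose and 2 fell (10 and 5 adjusted over the list alone; camera adjusted p = 9.48e-05; adjusted p = 0.0294 with an estimated correlation), with FOSB at 1.51, IER3 at 0.97 and MYC at 0.86.

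Of 23 actin and serum response genes 4 rose (7 adjusted over the list alone), including CCN2 (0.74), TPM1 (0.65) and TAGLN (0.66). The list's call (camera adjusted p = 0.000389) was lost at adjusted p = 0.164 with an estimated correlation. Of 23 stellate identity genes 2 rose (3 adjusted over the list alone), CD248 (0.54) and FAP, whose level before TGF-b is not shown to be above background, and that call (camera adjusted p = 0.0414) was lost at adjusted p = 0.123 with an estimated correlation. Among inflammatory genes IL1B, BIRC3 (-0.88) and TNFAIP3 (-0.63) fell while NFKBIZ rose (0.98), and the list did not pass (camera adjusted p = 0.501). By fry, JAK-STAT components (adjusted p = 0.00444) and interferon-stimulated genes (0.0106) were called downward, neither of them by camera (adjusted p = 0.071 and 0.0633). The number of changed genes was 390 when only these groups were fitted, 276 with the median of probe sets, 399 with the brightest probe set and 229 with a fold of at least 1.5. With the median of probe sets KRTAP1-5, FAM24B, IL1B, LOX, THBS1, TAGLN, VEGFA, FAP and CD248 no longer passed. KRTAP1-5 stood at only -0.412 there. FAP did not pass without control siRNA 0 h replicate 3 or 2 h replicate 1 or 3 (highest adjusted p = 0.0666), nor CD248 without 0 h replicate 3 or 2 h replicate 1 or 2 (0.0878).

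With STAT3 siRNA, TGF-b raised SKIL, JUNB, SNAI1 and PMEPA1, as it had with control siRNA. SKIL rose 3.51-fold, JUNB 3.34-fold, from 8.387 ± 0.0859 to 10.12 ± 0.0863 (SD, n = 3; limma adjusted p = 1.8e-07), SNAI1 2.97-fold and PMEPA1 2.91-fold. ANGPTL4 (1.39), IL11 (1.34), the thiamine transporter SLC19A2 (1.33), BHLHE40 (1.25), HIC1 (1.25) and LIF (1.24) completed the 10 largest rises. The largest falls were in KRTAP1-5 (-1.34), CITED2 (-0.96), PTX3 (-0.93), BMP4 (-0.93), NABP1 (-0.83), EVI2A (-0.81), NLRP10 (-0.72), LURAP1L (-0.71), IL1B (-0.70) and TNFSF4 (-0.69). In all, 190 genes rose and 59 fell, 20 and 1 of them at least 2-fold. Of the genes called with control siRNA, 156 also rose with STAT3 siRNA, where independent lists would share 3.36, and 50 also fell against 0.557. KRTAP1-5 did not pass without STAT3 siRNA 0 h replicate 1 or 2 h replicate 2 (highest adjusted p = 0.0592). The comparisons share no array but share each gene's estimate of the spread, which adds to the overlap, and 0 genes were called in opposite directions by limma (2950 and 2045 had an unadjusted p under 0.05). Dim genes, which seldom passed, are counted in the independent expectation and lower it.

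Of 26 TGF-b/SMAD targets 16 rose with STAT3 siRNA (21, and 1 fell, adjusted over the list alone; camera adjusted p = 1.55e-47; adjusted p = 0.000152 with an estimated correlation), and of 11 BMP targets 3 rose (5 adjusted over the list alone), ID1 by 0.89, SMAD6 by 0.59 and BAMBI by 0.33 (camera adjusted p = 6.42e-07; adjusted p = 0.0158 with an estimated correlation). Matrix genes rose in 3 of 42 cases, THBS1 (0.41), MMP2 (0.49) and ITGAV (0.32), and 15 rose and 1 fell adjusted over the list alone. The matrix call (camera adjusted p = 7.57e-06) was lost at adjusted p = 0.0562 with an estimated correlation. STAT3 targets rose in 6 of 36 cases (9, and 1 fell, adjusted over the list alone), with GADD45B at 0.84, SOCS3 at 0.79 and VEGFA at 0.64. Their call (camera adjusted p = 0.000392) was lost at adjusted p = 0.172 with an estimated correlation, and that of 23 actin genes (1 rose, 4 adjusted over the list alone; camera adjusted p = 0.0048) at adjusted p = 0.348 with an estimated correlation and 0.0616 by fry. Of 30 immediate-early genes 4 rose, also adjusted over the list alone, including FOSB (1.05), IER3 (0.61) and EGR2 (0.54), without a list call by camera (adjusted p = 0.103, upward, with a median of -0.02 and a mean of 0.12) but with one by fry (upward, adjusted p = 0.00195). The number of changed genes was 149 when only these groups were fitted, 88 with the median of probe sets, 144 with the brightest, 383 with an eBayes trend and 99 with a fold of at least 1.5. It was 164, 155 and 158 without STAT3 siRNA 0 h replicates 1, 2 and 3, and 150 without STAT3 siRNA 2 h replicate 1.

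Several of these calls depended on single arrays. ITGAV lost its call whichever of the 12 arrays was left out (highest adjusted p = 0.202), and BAMBI kept its call only without control siRNA 2 h replicate 1 (0.187). MMP2 did not pass without any STAT3 siRNA array except 0 h replicate 3 (0.0912). THBS1 did not pass without STAT3 siRNA 0 h replicate 2 or 3 or 2 h replicate 1 or 2 (0.0677), nor EGR2 without 0 h replicate 2 or 3 or 2 h replicate 2 or 3 (0.0866). With the median of probe sets KRTAP1-5, NABP1, LURAP1L, IL1B, ID1, SMAD6, BAMBI, THBS1, MMP2, ITGAV and VEGFA no longer passed. KRTAP1-5, the largest fall by the mean, stood at -0.535 there.

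After TGF-b, cells with STAT3 siRNA had less LIF, SNAI1 and SOCS3 transcript than control cells, and more ACTA2, COL1A2 and COL3A1. LIF was 2.14-fold lower, SNAI1 1.98-fold, KLF10 1.73-fold, JUNB 1.65-fold and IL11 1.62-fold, and SOCS3 was 2.45-fold lower, at 7.366 ± 0.0491 against 8.656 ± 0.0448 (SD, n = 3; limma adjusted p = 3.77e-07). ID1, a BMP target, was 2.05-fold lower. Part of these differences was present before TGF-b. At 0 h IL11 (-0.58), ID1 (-0.63) and SOCS3 (-0.44) were already lower with STAT3 siRNA (limma adjusted p = 0.000196, 0.000528 and 0.00079). With the median of probe sets ID1 stood at -0.634 at 0 h and no longer passed (limma adjusted p = 0.139). SNAI1 stood at 6.502 against 6.91 with control siRNA and LIF at 7.091 against 7.563, while JUNB was nearly equal at 8.387 against 8.444. ACTA2 stayed 2.90-fold higher, COL1A2 2.19-fold and COL3A1 2.07-fold. In all, 1610 genes were higher and 1555 lower. Of these, 971 had also been higher at 0 h and 1081 also lower, where independent lists would share 100 and 116, and 3 in each direction were called the opposite way. Here too each gene's estimate of the spread is shared, and dim genes lower the expected counts.

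The largest rises at 2 h included ALDH1L2 (2.19), B3GALT2 (1.98), ITGB3 (1.61), the lipid receptor S1PR1 (1.61), SLC7A11 (1.60), PSAT1 (1.54), RTL3 (1.48) and SLC24A3 (1.47). H2BC15 was higher too, again from a control level (2.811) not shown to be above background. The largest falls included GJA1 (-2.25), NID1 (-1.78), CXCL16 (-1.46), GALNT16 (-1.45, on 1 probe set), TP53INP2 (-1.42), the receptor kinase KIT (-1.37), VAT1L (-1.33), UHMK1 (-1.33), FAM91A1 (-1.31) and CASD1 (-1.30).

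The matrix list was higher at 2 h (22 rose and 1 fell of 42, 25 and 4 adjusted over the list alone; camera adjusted p = 1.02e-08; adjusted p = 0.0404 with an estimated correlation) and the sterol list lower (10 of 15 fell, 11 adjusted over the list alone; camera adjusted p = 3.29e-06; adjusted p = 0.0404 with an estimated correlation), with STARD4 at -0.56 and SREBF1 at -0.44. The stress response list had 12 of 21 higher and 1 lower (13 and 2 adjusted over the list alone; camera adjusted p = 1.70e-06; adjusted p = 0.0608 with an estimated correlation), including ASNS (1.03) and PHGDH (0.52). Actin genes were higher in 10 and lower in 2 of 23 cases (15 and 2 adjusted over the list alone; camera adjusted p = 4.82e-07; adjusted p = 0.0972 with an estimated correlation). Cell cycle genes were lower in 10 of 36 cases and higher in 1 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00132; adjusted p = 0.173 with an estimated correlation), with CCNE1 at -0.89.

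TGF-b/SMAD targets were lower in 10 and higher in 2 of 26 cases (13 and 2 adjusted over the list alone; camera adjusted p = 0.00253), STAT3 targets lower in 10 and higher in 3 of 36 (14 and 4 adjusted over the list alone; camera adjusted p = 0.00117), and BMP targets lower in 4 of 11 (4 and 1 higher adjusted over the list alone; camera adjusted p = 0.0121). Each of these calls was lost at adjusted p = 0.146 with an estimated correlation. Immediate-early genes were lower in 7 and higher in 1 of 30 cases (10 and 1 adjusted over the list alone), with EGR1 at -0.77 and NR4A1 at -0.69 (camera adjusted p = 0.0365; adjusted p = 0.173 with an estimated correlation). JAK-STAT components were called downward by fry (adjusted p = 0.00265) and not by camera (0.839). Of these 29 genes 2 were higher and 6 lower, with 7 each way adjusted over the list alone. The list's median was 0.00636 and its mean -0.0167, with 15 members above 0. Among endothelial and epithelial markers, CDH5 was higher by 0.64 and CLDN4 lower (-0.72), with no call for either list (camera adjusted p = 0.975 for both). Their medians and means differed in sign, at -0.06 and 0.00259 for endothelial and 0.06 and -0.02 for epithelial markers. The number of changed genes at 2 h was 1749 with the median of probe sets and 665 with a fold of at least 1.5. With the median of probe sets STARD4, SREBF1 and CLDN4 no longer passed.

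**Figure D2:**
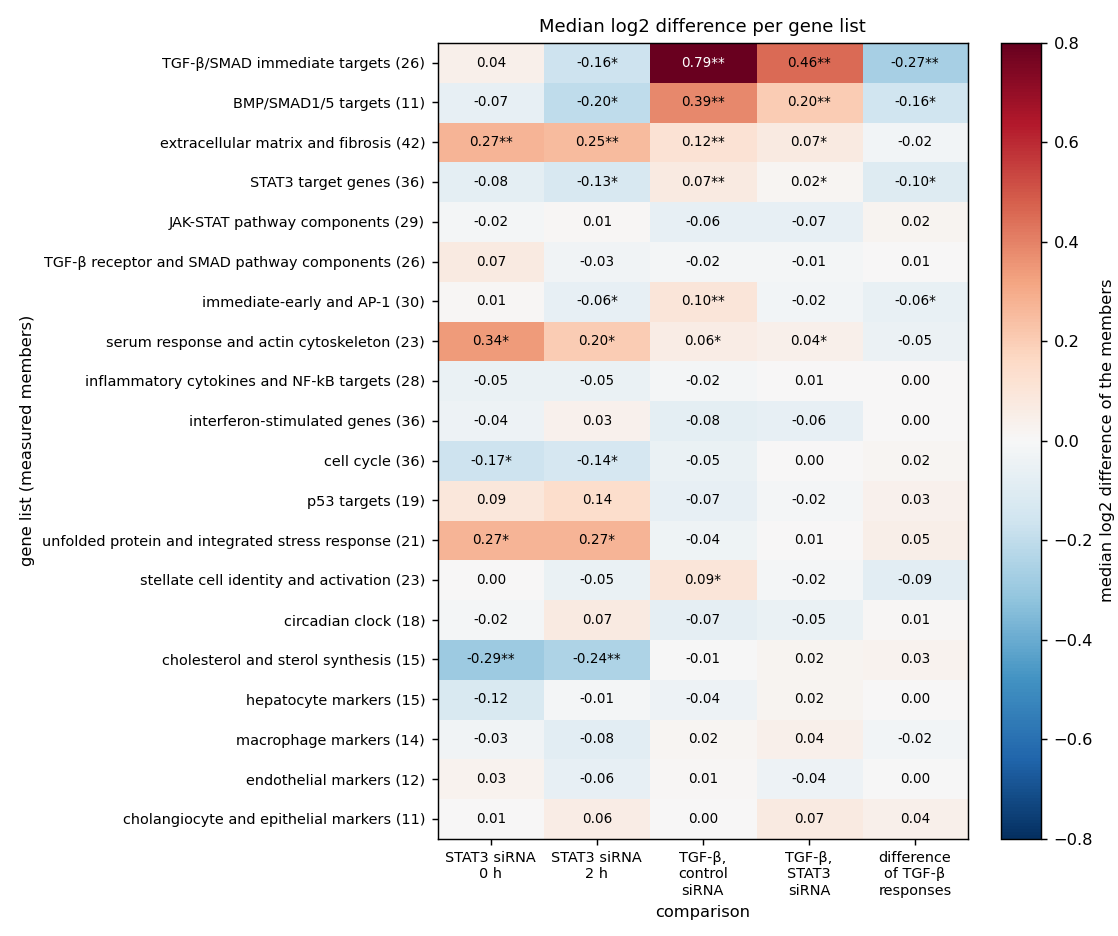
Median log2 difference (colour and number) of the measured members of the 20 gene lists (y axis, number of members in parentheses) in 5 comparisons (x axis). One asterisk marks a camera adjusted p under 0.05 and a pair of asterisks marks a call that also holds with an estimated correlation; TGF-b/SMAD targets have a median of 0.79 with control siRNA and 0.46 with STAT3 siRNA.

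The study's central question, whether the TGF-b response differs with STAT3 siRNA, was tested by the interaction. It called 4 genes. EDN1 rose by 2.07 with control siRNA and from 9.508 ± 0.0655 to 10.24 ± 0.125 (SD, n = 3) with STAT3 siRNA, a difference of the responses of -1.34 (limma adjusted p = 0.011), and its level without TGF-b was already higher with STAT3 siRNA. SOCS3 rose by 1.64 against 0.79, a difference of -0.85 (adjusted p = 0.011). The falls of CITED2 and PTX3 were smaller with STAT3 siRNA, by 0.75 each (adjusted p = 0.0322 and 0.0339).

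JUNB (-0.67), SNAI1 (-0.58), LIF (-0.63) and GADD45B (-0.59) had smaller estimated rises with STAT3 siRNA without passing (adjusted p = 0.0848 for each), as did MYC (-0.74, adjusted p = 0.138). GADD45B had started higher with STAT3 siRNA (9.784 against 9.215) and ended nearly equal (10.62 against 10.65). MYC also had a higher starting estimate (8.245 against 7.935), while JUNB, SNAI1 and LIF did not. ZFP36, on 2 probe sets, had an estimated response of 0.69 with control siRNA and -0.12 with STAT3 siRNA (interaction -0.81, adjusted p = 0.0505). RHOB (-0.65) and the histone demethylase gene KDM6B (-0.70), chosen after their values were seen, stood at adjusted p = 0.0503. As a list, TGF-b/SMAD targets responded less with STAT3 siRNA, with a median interaction of -0.27 over 26 genes (1 smaller by the single-gene test, 11 smaller and 1 larger adjusted over the list alone; camera adjusted p = 8.77e-14; adjusted p = 0.0127 with an estimated correlation). The lists of STAT3 targets (camera adjusted p = 9.12e-05; adjusted p = 0.105 with an estimated correlation), BMP targets (0.00205; adjusted p = 0.104 with an estimated correlation) and immediate-early genes (0.00179; adjusted p = 0.104 with an estimated correlation) had calls that were lost. JUNB stands in the TGF-b/SMAD, STAT3 target and immediate-early lists. Adjusted over the list alone, 5 STAT3 targets, 3 BMP targets and 7 immediate-early genes had a lower interaction. Matrix genes did not pass (median interaction -0.02, camera adjusted p = 0.358), nor did actin genes (-0.05, camera adjusted p = 0.24).

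As a set, the genes induced by TGF-b responded less with STAT3 siRNA. The 524 genes induced by the averaged effect had a median response of 0.44 with control siRNA and 0.32 with STAT3 siRNA, a ratio of 0.722, and 401 of them (76.5%) had a lower estimated response with STAT3 siRNA. The median change of the response was -0.13 (exact permutation p = 0.005 over 400 relabellings, the smallest p they allow). Effects of the siRNA that do not depend on TGF-b also move the relabelled medians, so this p does not isolate the response. The 291 repressed genes had a median response of -0.38 and -0.27, a ratio of 0.721, and 230 of them (79.0%) had a less negative one with STAT3 siRNA, with a median signed change of -0.12 (exact permutation p = 0.025). The repressed genes' value had an exact permutation p = 0.055 without control siRNA 2 h replicate 1 (-0.15), 2 (-0.16) or 3 (-0.16), and p = 0.05 without STAT3 siRNA 0 h replicate 3 (-0.15). It also did not pass with the median of probe sets (-0.13, exact permutation p = 0.11), the brightest probe set (-0.14, p = 0.07) or dim probe sets left out (-0.10, p = 0.075). The induced genes' value was -0.22 with the median of probe sets and -0.23 with the brightest (exact permutation p = 0.005 for both). In 20 sets of simulated arrays without an interaction the medians lay between -0.0134 and 0.0109. Noise was drawn independently for each gene there. Genes that vary together would widen that range, so it does not show how far chance could move the medians.

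**Figure D3:**
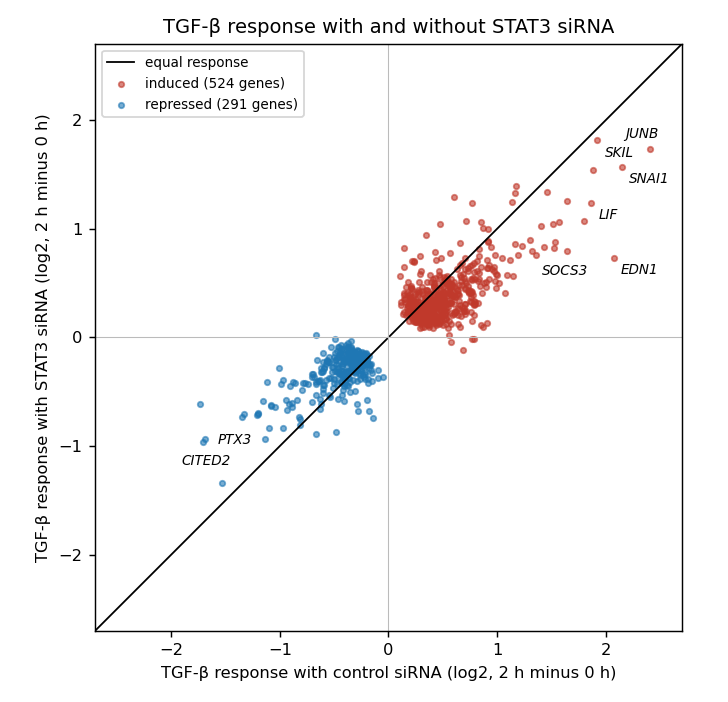
TGF-b response (log2, 2 h minus 0 h) with control siRNA (x axis) and with STAT3 siRNA (y axis) of the 524 induced and 291 repressed genes, 1 point per gene, chosen by the averaged response. The line marks equal responses, and 401 induced genes lie below it and 230 repressed genes above it.

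The single-gene interaction calls were fragile. None of the 4 genes passed without control siRNA 0 h replicate 2 or without STAT3 siRNA 2 h replicate 2, where the adjusted p of EDN1 and SOCS3 reached at most 0.059 and 0.0606 and those of CITED2 and PTX3, over all left-out arrays, at most 0.116 and 0.124. SOCS3 also did not pass without control siRNA 0 h replicate 3 or 2 h replicate 3, CITED2 passed only without replicate 3 of either STAT3 siRNA group, and PTX3 only without STAT3 siRNA 0 h replicate 3. With the median of probe sets EDN1 alone passed (adjusted p = 0.0111), against 0.641 for SOCS3, 0.562 for CITED2 and 0.705 for PTX3. The estimates kept their direction there, at -0.68 for SOCS3, 0.69 for CITED2 and 0.54 for PTX3. With the brightest probe set limma called 0 genes, with 1390 at an unadjusted p under 0.05, against 28 with an eBayes trend.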

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

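The tests of the starting level and of siRNA specificity were chosen only after the results were seen. Results that differed between the siRNAs by a test of the difference itself were singled out here. These were the TGF-b responses of EDN1 (-1.34), SOCS3 (-0.85), CITED2 (0.746) and PTX3 (0.751), given as the response with STAT3 siRNA minus that with control siRNA. The median signed change of the response, whose p does not isolate the difference, was -0.125 for induced and -0.116 for repressed genes.

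The smaller TGF-b response with STAT3 siRNA was weighed against 3 explanations. Compressed signal on the arrays with STAT3 siRNA at 2 h would shift unresponsive genes of the same level alike, and the 524 such genes matched to the induced ones had a median of 0.0391 (0.0197 to 0.0425 with 1 array left out), on the other side of 0, while those matched to repressed genes had -0.0191 (-0.0336 to -0.000257), nearer 0 than the repressed genes. A higher starting level with STAT3 siRNA could limit a further rise. The 225 induced genes that started no higher still responded less, with a median of -0.0848 (-0.117 to -0.059 with 1 array left out). A higher start is therefore not the whole cause of the smaller rises. For EDN1 and other genes that started higher, this stays open. The reverse case, repressed genes with a lower starting level, was not tested. With 1 STAT3 siRNA in the design, loss of STAT3 and effects of the siRNA on other genes cannot be told apart.

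Other assignments of the same arrays were compared with the real groups. For the averaged TGF-b effect, a chance assignment of these arrays is an unlikely source. Of 100 drawn assignments of the times within each siRNA, 1, the real one, gave as many genes, with 815 against at most 34. The draw cannot give a share under 1 in 100. It also cannot reach differences between cultures, since no label says that the samples of a group were separate cultures. For the interaction, 2 of 100 drawn assignments of the siRNAs within each time gave as many, with 4 real calls and 4 in the highest other. The siRNA effects widen the spread in those other assignments and lower their counts, so whether chance gave the 4 calls is left open. The comparisons of 3 against 3 arrays have 10 splits each, too few for a share under 0.05, with 3047 genes in the real split against at most 0 in any other for STAT3 siRNA at 0 h, 604 against 1 for TGF-b with control siRNA, 249 against 0 for TGF-b with STAT3 siRNA and 3165 against 1 for STAT3 siRNA at 2 h.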

How the results depend on the processing

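Leaving out dim probe sets was chosen after the data were seen, as were the trend, robust, centred and brightest alternatives for STAT3 and the response, the filter and the fit of only the groups compared for STAT3, and the median of probe sets for the response. STAT3 stayed lower and past the threshold in all of these it was fitted with, and with the block, quantile normalization, the median of probe sets or any 1 array left out, from -0.756 to -0.994 at 0 h and from -0.78 to -1.04 at 2 h. The median change of the induced response passed in those run for it, and with the filter, the block, quantile normalization or any 1 array left out (-0.119 to -0.168), over a range from -0.102 to -0.233. That of repressed genes was -0.127 with the median of probe sets, -0.142 with the brightest and -0.0993 without dim probe sets (exact p = 0.11, 0.07 and 0.075, no call), ranged from -0.0922 to -0.167 with 1 array left out and lost its call without any one control siRNA 2 h array (-0.149, -0.159 and -0.159, exact p = 0.055) or without STAT3 siRNA 0 h replicate 3 (-0.15, exact p = 0.05). The median of probe sets gave fewer changed genes (STAT3 siRNA 1718 at 0 h and 1749 at 2 h, TGF-b 276 with control and 88 with STAT3 siRNA, 432 averaged, interaction 1), as did the brightest probe set (TGF-b 399, 144 and 508, interaction 0) and a fold of at least 1.5 (635, 665, 229, 99 and 142). Fitting only the groups compared, with fewer residual degrees of freedom, gave 390 and 149 genes for TGF-b. An eBayes trend gave 383 for TGF-b with STAT3 siRNA. The interaction gave 28 with the trend, 18 without the lowest 40% of genes (fewer tests) and 23 without dim probe sets. Except for the constructions named, the cause was not tested. With 1 array left out, TGF-b with STAT3 siRNA gave 150 to 233 genes and the interaction 0 to 5. The interaction gave 2 without control siRNA 0 h replicate 1, 0 without replicate 2 and 1 without replicate 3, 2 and 1 without control siRNA 2 h replicates 2 and 3, 2 without STAT3 siRNA 0 h replicate 1 or 2, and 0 without STAT3 siRNA 2 h replicate 2. Where limma gave 0, unadjusted p was under 0.05 for 1390 genes (brightest probe set), 1339 (control siRNA 0 h replicate 2 left out) and 1584 (STAT3 siRNA 2 h replicate 2 left out). Chance alone would put about a 0.05 share of all genes there, which is most of each count. With the replicate block the counts were 2721 and 2807 for STAT3 siRNA at 0 h and 2 h, 523 and 199 for TGF-b, 664 averaged and 2 for the interaction (EDN1 and SOCS3; CITED2 and PTX3 had adjusted p = 0.132). No label pairs the replicate numbers, the 18 same-number correlations lay between -0.0824 and 0.07, and 1 of 12 arrays correlated best with its own number. Of 263 passing calls of named genes, 223 held without each array in turn, 262 with quantile normalization, 249 with the replicate block and 183 with the median of probe sets; no list called by camera turned direction with an estimated correlation, fry, the block or quantile normalization. Probe sets near the bottom of the scale and groups of 3 arrays limit small changes.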

Other observations

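The tests of the overlap of TGF-b and siRNA effects and of probe sets outside the gene table were chosen only after the results were seen. The lists of the amino acid and chaperone arms were written after the fixed stress response list had been examined, and their tests were set before any value of their genes was seen. TGF-b-responsive genes were also frequent among the genes that STAT3 siRNA changed, in both directions. Of the 524 induced genes, 142 were higher and 127 lower with STAT3 siRNA averaged over both times, where independent lists would give 57.4 and 60. Of the 291 repressed genes, 94 were higher and 66 lower, against 31.9 and 33.3. The averaged siRNA effect called 4988 genes. The averages over siRNA and over time are independent contrasts of the same arrays, but share each gene's estimate of the spread, which adds to the overlap in both directions. The expected counts also spread the calls evenly over all 22260 genes. Without the lowest 40% of genes, 13356 were left. They held 752 of the 815 TGF-b calls and 2772 of the 3047 calls for STAT3 siRNA at 0 h. Dim genes thus lower the expected counts, and the excess over them is overstated by an amount not computed.

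PSAT1, ASNS and SLC7A11 rose with STAT3 siRNA, and a candidate explanation is that the amino acid arm of the integrated stress response is higher as a whole. Of 20 measured genes of that arm outside the fixed list, 12 rose and 1 fell at 0 h, with a median log2 difference of 0.326 (0.318 to 0.337 with 1 array left out; camera p = 4.1e-09, p = 0.00068 with an estimated correlation), and 14 rose and 1 fell at 2 h (median 0.422). NUPR1 (0.85), the amino acid transporters SLC1A5 (0.69) and SLC7A5 (0.65), and the folate enzyme MTHFD2 (0.59), chosen after their values were seen, had the largest rises at 0 h, while SLC38A2 fell (-0.26). A general unfolded protein response would raise the chaperone arm too. Of 18 measured genes of that arm outside the fixed list, 3 rose and none fell at 0 h: SEC24D (0.44), PDIA5 (0.395) and LMAN1 (0.255). At 2 h 2 rose, SEC24D (0.44) and PDIA5 (0.43), and 1 fell, SSR3 (-0.26). All of these were chosen after their values were seen. Members of the fixed list, such as XBP1, were not among the 18. The median of the 18 genes was -0.0724 at 0 h (-0.0974 to -0.0439 with 1 array left out) and -0.13 at 2 h (-0.131 to -0.0961). These 18 chaperone arm genes were thus not higher as a set. With single members called upward and a range from -0.451 to 0.44 at 0 h, these medians do not settle whether this response contributed in part. A higher amino acid arm is a hypothesis from 1 STAT3 siRNA, and what raised the amino acid genes was not tested.

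Probe sets outside the gene table, 93635 with several symbols or none listed, also changed. limma called 585 for STAT3 siRNA at 0 h, 409 of them unlisted, and 521 at 2 h. TGF-b with control siRNA changed 86. For TGF-b with STAT3 siRNA and for the interaction 0 were called, with 5084 and 4914 at an unadjusted p under 0.05. Chance alone would put about a 0.05 share of these probe sets there, close to both counts.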
